A study of Mus musculus with 36 samples.

How the data were processed

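The measurements were RNA sequencing of motor neurons made from mouse embryonic stem cells, per the labels' protocols. Cells carried eGFP, or eGFP and CD2, under the HB9 promoter, were labelled with an antibody against CD2 and were collected on a magnetic column. They were then kept for 1 or 3 days in medium conditioned by astrocytes from spinal cord or cortex of newborn pups, per the labels' protocols. Which of these sources gave the medium of each library is not given in the sources used here, so an effect of the source could not be separated. The astrocyte cultures were described there as 95% GFAP-positive, microglia were shaken off, and no neurons or oligodendrocytes were detected by staining. Every medium received glucose, antibiotics, GDNF, BDNF and CNTF and was filtered before use. Media came from non-transgenic (NTg), mutant SOD1 (mSOD1) and wild-type SOD1 (wtSOD1) astrocytes, with 6 libraries per medium and day. Total RNA was used for standard Illumina libraries, per the labels' protocols. The series description names a time zero control, which was not analysed here.

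The deposited files hold whole-number read counts per gene for each library, per the file headers, and the submitters' processing notes name TopHat 1.3.3, DESeq and the mouse build mm9. The counting program, the annotation and the strandedness are not given in the sources used here. A second deposited column, headed VSE per the file headers, holds the authors' transformed expression on a log2-like scale. Its values rose by 0.928 to 0.99 per doubling of reads at 500 reads or more. Genes without a read averaged 4.49 there, with an SD between libraries of 0.206, so the authors' transformation holds more than the reads. The main tests used the counts, and the log2-like values served as an alternative only. The files list 21761 genes, of which 1798 had no read in any library and 7 had no symbol. The labels' protocols name no statistical model.

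Library totals are given with the results. They ran from 4.39 to 88.9 M reads, and 16465 to 18506 genes had at least 1 read per library. Counts were tested with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood F-tests with robust fits, TMM scaling and filterByExpr by group, which kept 15207 genes. All 36 libraries entered 1 fit of 6 group means with 30 residual degrees of freedom and no block, and 11 comparisons were drawn from it: 6 between media within a day, 3 between days within a medium and 2 interactions of time with medium. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Folds are log2 estimates with their standard error. Levels are counts per M reads (CPM) on TMM-scaled library sizes, computed here, with a prior count of 2 where logarithms were taken.

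The comparisons, the test, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Named genes had an adjusted p below 0.05, an average log2 CPM of at least 1 and the same direction in at least 5 of 6 same-numbered pairs, and up to 10 were taken per direction by fold. Where fewer than 10 genes passed, the same rule was applied to the fit with the replicate block and then to the lowest p-values. Up to 4 members of each list described, up to 10 genes with the lowest p per interaction, and Sod1, Mnx1, Isl1, Chat, Gfap, Aif1, Col1a1, Mki67 and Nfkbia were reported whatever their value. Some genes that these rules select are not reported here. Genes whose level in single libraries is described were chosen after their values were seen.

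Gene lists were written from general knowledge of the cells and of the question. They covered neuronal, stress, inflammatory, metabolic, signalling and cell type genes, 40 lists with 916 entries, of which 913 matched a gene, 11 of them through gene identifiers. Lists with at least 5 tested members (39 of 40) were tested with camera at a preset correlation of 0.01, two-sided, adjusted over all lists and 11 comparisons. The same tests were run with an estimated correlation between genes, with the replicate block, and with fry. Members past the threshold were counted with p-values adjusted over all genes and, beside it, over the list alone. Genes that overlap on the chromosome or have near-identical paralogs were named as uncertain, since the treatment of shared reads is not given in the sources used here. Overlaps were looked up in a GRCm38 annotation by gene identifier, and no coordinates were converted.

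The labels give each library an experiment number from 1 to 6, which was read as a shared experiment, so libraries with the same number in different groups form pairs. Deviations of same-numbered libraries from their group means had a mean correlation of 0.132 on day 1 (11 of 18 pairs over 0.1) and 0.24 on day 3 (16 of 18), against -0.026 and -0.048 for different numbers, and 0.037 across days. Values with experiment as a block are printed beside a result where they change its call or move its count by more than 1.5 times.

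Alternatives planned before the data were examined were DESeq2 1.42.0 Wald tests, DESeq2 size factors in edgeR, no filter on low counts, experiment as a block, fits of only the groups compared, limma-voom with sample weights (limma 3.58.1), and leaving out each experiment in turn. Chosen after seeing the data were leaving out NTg replicate 6 of day 1, wtSOD1 replicate 4 of day 1 or both, a block within each day, and limma on the authors' log2-like values. For comparisons that share NTg libraries, overlap and covariance were set beside 10 simulations per day without any effect, beside 10 in which the called effects of each medium were kept and those of wtSOD1 moved to other genes of similar level, which were added after the overlap was seen, and beside fits that gave each comparison 3 of the 6 NTg libraries. Other splits of the same libraries into groups were refitted for each comparison, 100 with the real one, and 32 that part every same-numbered pair.

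The test was tested on data simulated for all 36 libraries from a fit of the 6 groups with experiment as a block (15167 genes). In it the mSOD1 means of day 3 were set to those of NTg, and each experiment had the same effect on both days. The changed genes were drawn from those with an average log2 CPM above 1, so the shares found hold for such genes only. With edgeR, 65.7% of 67 genes changed 1.25-fold, 88.1% of 67 changed 1.5-fold and 100% of 66 changed 2-fold were found, with 1 false call. With the block, 71.6%, 95.5% and 100% were found with 10 false calls. DESeq2 (15207 genes) found 71.6%, 92.5% and 100% with 2 false calls, and voom 68.7%, 88.1% and 98.5% with 1. Changes smaller than 1.25-fold were not simulated, and a gene that does not pass is not shown to be unchanged. Within groups no library was a copy of another: the closest replicates, mSOD1 5 and 6 of day 3, differed with a chi-square of 2.3 per degree of freedom.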

Results

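RNA sequencing of 36 libraries measured gene expression in mouse motor neurons. The neurons came from embryonic stem cells in which the promoter of HB9 (Mnx1), a motor neuron gene, drives eGFP, or eGFP and the surface protein CD2. Cells bearing CD2 were collected on a magnetic column and kept in medium conditioned by astrocytes of newborn mice. The astrocytes were non-transgenic (NTg), carried mutant SOD1 (mSOD1), the enzyme altered in a familial form of amyotrophic lateral sclerosis (ALS), or over-expressed wild-type SOD1 (wtSOD1). RNA was taken after 1 or 3 days, giving 6 groups of 6 libraries, and the replicate numbers are experiments 1 to 6 of the labels. Reads assigned to genes on day 1 came to 14.3, 19.7, 17.9, 10.8, 18 and 4.39 M reads in the NTg libraries 1 to 6. The mSOD1 libraries of that day held 11.8, 12.4, 14.1, 8.58, 13.1 and 18.8 M and the wtSOD1 libraries 20.7, 13.2, 17.8, 88.9, 10.5 and 11.1 M. On day 3 the totals were 42.2, 16.2, 15.4, 11.6, 12.2 and 12.8 M for NTg, 11.6, 10.5, 16.9, 13.1, 13.3 and 12.3 M for mSOD1, and 15.6, 23.1, 11.6, 13.7, 12.9 and 13.6 M for wtSOD1.

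Markers of motor neurons were read in each group. Chat (gene 12647), which makes acetylcholine, averaged 223 ± 24 counts per M reads (CPM; mean ± SD, n = 6) in NTg medium on day 1 and 81.8 ± 13 CPM on day 3. Slc18a3 lies inside it, so reads of Slc18a3 may be counted for Chat as well. Group means ran from 32.5 to 112 CPM for Mnx1 and from 55.2 to 160 CPM for Isl1. Sod1 (20655) was even across groups, from 38.9 ± 1.3 CPM in mSOD1 medium on day 3 to 45.1 ± 6.5 CPM in NTg medium on day 3. Aif1, a microglial gene, was too low to test, with group means of 0.237 to 0.355 CPM. The first principal component carried 58% of the variance and separated the days, with day 1 libraries at -45.6 to -31.5 and day 3 libraries at 20.8 to 49.3. A pair of libraries stood apart from their groups: NTg replicate 6 of day 1, the smallest library, on the second component (57.8, all others at most 7.8), and wtSOD1 replicate 4 of day 1, the largest, on the next (-39.4).

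**Figure D1:**
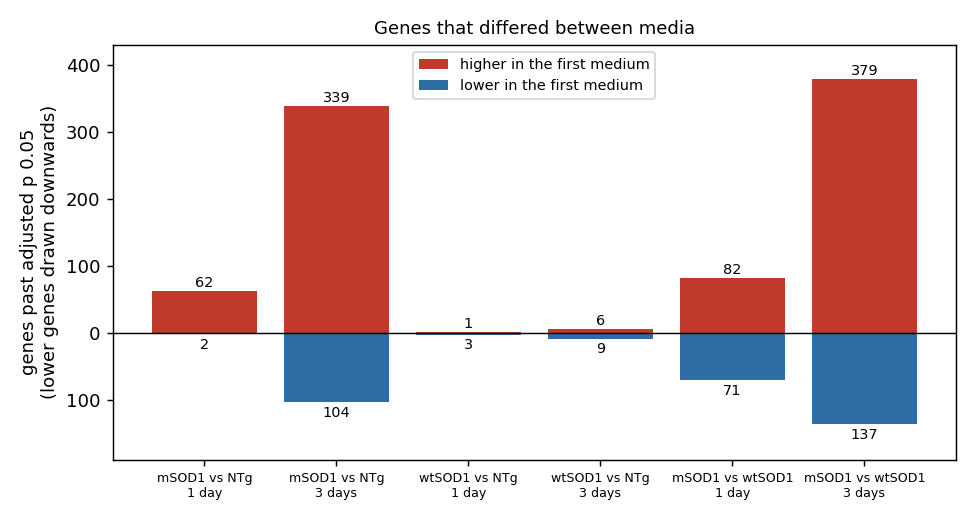
Numbers of genes past adjusted p 0.05 (edgeR, y axis) for each pair of media on each day (x axis, 6 libraries per group). Red bars count genes higher and blue bars, drawn downwards, genes lower in the first-named medium, 339 and 104 for mSOD1 against NTg on day 3.

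What did 1 day of mSOD1 medium change in the motor neuron cultures, relative to NTg medium? Genes of the interferon and NF-kB responses were among those that rose, and no test assigned the rises to a cell type. Irf9 (16391), the DNA-binding subunit of the interferon-activated complex ISGF3, went from 20.5 ± 2.1 to 40.5 ± 4 CPM (log2 difference 1.00 ± 0.07, estimate ± SE, n = 6 per group, adjusted p = 2.67e-12, higher in 6 of 6 same-numbered pairs). Usp18 (24110), a protease that restrains interferon signalling, rose by 2.46 ± 0.21 (adjusted p = 4.32e-10, 6 of 6), and Oasl2 (23962), an antiviral protein, by 2.34 ± 0.23 (1.59e-08, 6 of 6). Among chemokines, Ccl2 (20296), which draws monocytes, rose by 2.58 ± 0.33 (7.55e-06, 6 of 6), Cxcl10 (15945), which draws T cells, by 2.64 ± 0.40 (8.76e-05, 6 of 6) and Cxcl1, which draws neutrophils, by 3.08 ± 0.43 (1.37e-05, 6 of 6). Art3 overlaps Cxcl10 and Cxcl11 in the annotation, so its rise of 2.55 ± 0.36 (3.11e-05) cannot be assigned to a single gene. Nfkbia (18035), the inhibitor that NF-kB induces, rose by 1.61 ± 0.20 (2.88e-06, 5 of 6) and Vcam1, an adhesion molecule, by 0.75 ± 0.10 (1.37e-05, 6 of 6). The cytosolic RNA sensors Ddx58 and Ifih1 rose by 1.11 ± 0.11 (1.59e-08) and 1.47 ± 0.21 (1.8e-05), each in 6 of 6 pairs. Without NTg replicate 6 the log2 differences of Ccl2, Cxcl10 and Art3 were 3.17, 3.31 and 3.19.

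Of 23 interferon-stimulated genes tested, 15 rose and 8 did not pass (17 rose when adjusted over the list alone), and the list differed as a set (camera adjusted p = 8.13e-83, adjusted p = 9.12e-07 with an estimated correlation). Of 23 NF-kB targets and subunits, 10 rose and 13 did not pass (15 rose over the list alone, 2.99e-37, adjusted p = 4.23e-05 with an estimated correlation). Altogether 62 genes rose and 2 fell, 35 of the 64 by more than 2-fold, against 76 and 16 with DESeq2 and 81 and 8 with replicate as a block. A block within each day, chosen after the data were seen, gave a less one-sided split of 131 and 58. Among p53 targets, 1 of 24 rose, Cdkn1a, the cell cycle inhibitor p21 (0.31 ± 0.07, 0.0125, 6 of 6), and the list was higher as a set (1.2e-05, adjusted p = 0.167 with an estimated correlation). Of the cholesterol synthesis list, 1 of 24 fell, Insig1 (231070), which holds back the lipid gene regulator SREBP (-0.19 ± 0.05, 0.0485, lower in 5 of 6 pairs, 0.0563 without the pair of libraries that stood apart). That list was lower as a set (0.000815, adjusted p = 0.542 with an estimated correlation). The other gene that fell, 9430038I01Rik, has no function given in the sources used here (-0.63 ± 0.15, 0.0309). Ribosomal proteins were higher as a set (0.00212, adjusted p = 0.757 with an estimated correlation), their lowest p belonging to Rpl22 (0.07 ± 0.04, adjusted p = 0.798). Spinal Hox genes, which place neurons along the cord, were lower as a set (0.00986, adjusted p = 0.349 with an estimated correlation), with Hoxb3 at -0.26 ± 0.08 (0.345). Mnx1 (15285) and Isl1 (16392), transcription factors of motor neuron identity, stood at -0.08 ± 0.13 (0.949) and -0.07 ± 0.10 (0.941), and Chat at -0.04 ± 0.10 (0.982).

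NTg replicate 6 of day 1 carried more inflammatory transcripts than the other NTg libraries. Cxcl10 stood at 12 CPM against 0.515 to 2.85 in the other 5, and Ccl2 at 23.6 CPM against 2.77 to 4.17. The oligodendrocyte list was lower in mSOD1 medium with that library (0.00509, adjusted p = 0.477 with an estimated correlation) and not without the pair of libraries that stood apart (0.765). Without replicate 6 of NTg on day 1, 83 genes passed instead of 64.

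What separated mSOD1 from NTg medium on day 3? Fewer interferon genes passed than on day 1, and the receptors Osmr, Lifr and Il6st rose. Osmr (18414), the oncostatin M receptor, went from 30.6 ± 2.7 to 44.4 ± 3.9 CPM (log2 0.53 ± 0.07, adjusted p = 2.72e-06, 6 of 6 pairs). Lifr, the LIF and CNTF receptor, rose by 0.38 ± 0.07 (0.00439, 6 of 6), their partner Il6st by 0.22 ± 0.04 (0.00464, 6 of 6) and Socs2, a brake on cytokine signalling, by 0.35 ± 0.07 (0.00464, 6 of 6). Among the largest rises were Ifi202b (26388), an interferon-inducible DNA-binding protein with close paralogs, by 1.86 ± 0.29 (0.000234, 6 of 6), and Serpina3n, a protease inhibitor of a family with near-identical members, by 0.99 ± 0.18 (0.00367, 6 of 6). Csf2rb2, a cytokine receptor chain, rose by 0.98 ± 0.20 (0.00464, 6 of 6) and Reg3b (18489), a secreted lectin made by injured neurons, by 0.95 ± 0.14 (0.00017, 6 of 6). Ifi27l1 and Ifi27l2a overlap, and their shared rise of 0.89 ± 0.09 (2.57e-08) may be a single signal. Among the largest falls were Tcfap2b (21419), a transcription factor of neural crest and kidney, by 1.29 ± 0.25 (0.00439, 6 of 6), and Dhrs3, which reduces retinal and overlaps Vps13d, by 1.18 ± 0.28 (0.0191, 6 of 6). Slc7a3 (11989), an arginine and lysine carrier that overlaps Snx12, fell by 0.96 ± 0.23 (0.0189, 6 of 6). Altogether 339 genes rose and 104 fell, 6 of the 443 by more than 2-fold.

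Neuronal lists were higher as sets in mSOD1 medium on day 3, with 1 to 4 members of each past the threshold, and lost the call with an estimated correlation. Of 22 pan-neuronal genes, 3 rose and 19 did not pass (13 rose over the list alone, 8.52e-11, adjusted p = 0.344 with an estimated correlation). They were the RNA-binding proteins Elavl2 (0.31 ± 0.07, 0.0119) and Elavl4 (0.28 ± 0.07, 0.0233) and the microtubule regulator Stmn2 (0.32 ± 0.08, 0.0231), each higher in 6 of 6 pairs. Of 20 sodium and calcium channel genes, 4 rose (11 over the list alone, 2.58e-08, adjusted p = 0.317 with an estimated correlation). Of 16 ionotropic glutamate receptors 2 rose, Grin2a by 0.69 ± 0.18 and Grid1 by 0.46 ± 0.12 (6 over the list alone, 2.26e-05, adjusted p = 0.379 with an estimated correlation). Of 20 potassium channels 1 rose (3 without the pair of libraries that stood apart), Kcnab1 by 0.30 ± 0.08 (7 over the list alone, 3.66e-05, adjusted p = 0.353 with an estimated correlation). Of 22 synaptic vesicle genes 1 rose, Syn2, a synapsin, by 0.24 ± 0.06 (11 over the list alone, 4.21e-07, adjusted p = 0.35 with an estimated correlation).

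The lists of axon guidance, axon injury and STAT3 response were also higher as sets, though few of their members passed. Of 31 axon guidance genes 8 rose, among them the receptors Ephb1 (0.47 ± 0.09, 0.00355) and Unc5c (0.46 ± 0.12, 0.0289), and 12 over the list alone (2.94e-05, adjusted p = 0.298 with an estimated correlation). Of 24 axon injury genes 2 rose (4 without the pair of libraries that stood apart), Lifr and Gfra1 (14585), a GDNF receptor (0.47 ± 0.09, 0.00487, 6 of 6). Over that list alone 12 rose and 2 fell (2.53e-05, adjusted p = 0.167 with an estimated correlation). Of 17 STAT3 response genes 4 rose (10 over the list alone, 3.78e-07), and this list alone of those higher on day 3 kept its call (adjusted p = 0.0464 with an estimated correlation). Of 23 interferon-stimulated genes 1 rose, Irf9, by 0.35 ± 0.07 (0.00705, 6 of 6), and 2 over the list alone (0.0249, adjusted p = 0.638 with an estimated correlation).

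Lists of the amino acid response, fatty acid synthesis, proliferation and mesenchyme were lower as sets in mSOD1 medium on day 3. Of 25 genes of the amino acid response driven by ATF4, 9 fell and 16 did not pass (14 fell over the list alone, 6.23e-10, adjusted p = 0.0972 with an estimated correlation). They included Chac1 (69065), which breaks down glutathione (-0.66 ± 0.18, 0.0387), Mthfd2 of mitochondrial folate metabolism (-0.34 ± 0.06, 0.00309) and Slc7a5, a carrier of large amino acids (-0.30 ± 0.06, 0.00855), all lower in 6 of 6 pairs. Of 24 unfolded protein response genes 1 fell, Herpud1 (-0.26 ± 0.06, 0.0152), and 5 without the pair of libraries that stood apart, and over the list alone 10 fell and 1 rose (5.44e-05, adjusted p = 0.167 with an estimated correlation). Of 13 fatty acid synthesis genes 4 fell, led by Scd1 (20249), which desaturates fatty acids (-0.45 ± 0.07, 0.000311, 6 of 6), and 6 over the list alone (0.000471, adjusted p = 0.0529 with an estimated correlation). Of 31 proliferation genes 2 fell, the replication factors Mcm2 (-0.37 ± 0.07, 0.00522) and Mcm5 (-0.37 ± 0.09, 0.0191), and 22 fell over the list alone (1.18e-15, adjusted p = 0.344 with an estimated correlation). Of 18 mesenchyme genes 3 fell, among them the collagen Col1a2 (-0.49 ± 0.13, 0.0305), and 7 over the list alone (2.17e-05, adjusted p = 0.353 with an estimated correlation). Ribosomal proteins were lower as a set (6.54e-07, adjusted p = 0.558 with an estimated correlation), as were neural progenitor genes (0.000976, adjusted p = 0.558 with an estimated correlation), with Sox3 at -0.40 ± 0.12 (0.0679, 0.00846 with the block). NRF2 targets were lower as a set (0.017, adjusted p = 0.545 with an estimated correlation), with Nqo1 at -0.59 ± 0.25 (0.186). Heat shock genes were at the threshold (0.0479, adjusted p = 0.566 with an estimated correlation, 0.0523 without the pair of libraries that stood apart, 0.0695 with the block), with Hspd1 at -0.11 ± 0.05 (0.199).

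Mnx1, Isl1 and Chat did not pass between mSOD1 and NTg medium on day 3: Mnx1 stood at 0.06 ± 0.14 (0.846), Isl1 at 0.02 ± 0.11 (0.946) and Chat at 0.27 ± 0.10 (0.135, 0.0219 with replicate as a block). Of 24 motor neuron identity genes 4 rose, Gfra1, Ret (0.31 ± 0.08, 0.0228), Nrg1 (0.26 ± 0.07, 0.0457) and Foxp1 (0.26 ± 0.07, 0.0406), and the list did not pass as a set (0.0824, 0.0389 with the block). Mki67 (17345), a marker of dividing cells, stood at -0.21 ± 0.11 (0.281, 0.0157 with the block) and Sod1 at -0.21 ± 0.08 (0.129). The 443 genes became 32 without replicate 3 and 388 without replicate 1, and 1511 with replicate as a block.

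**Figure D2:**
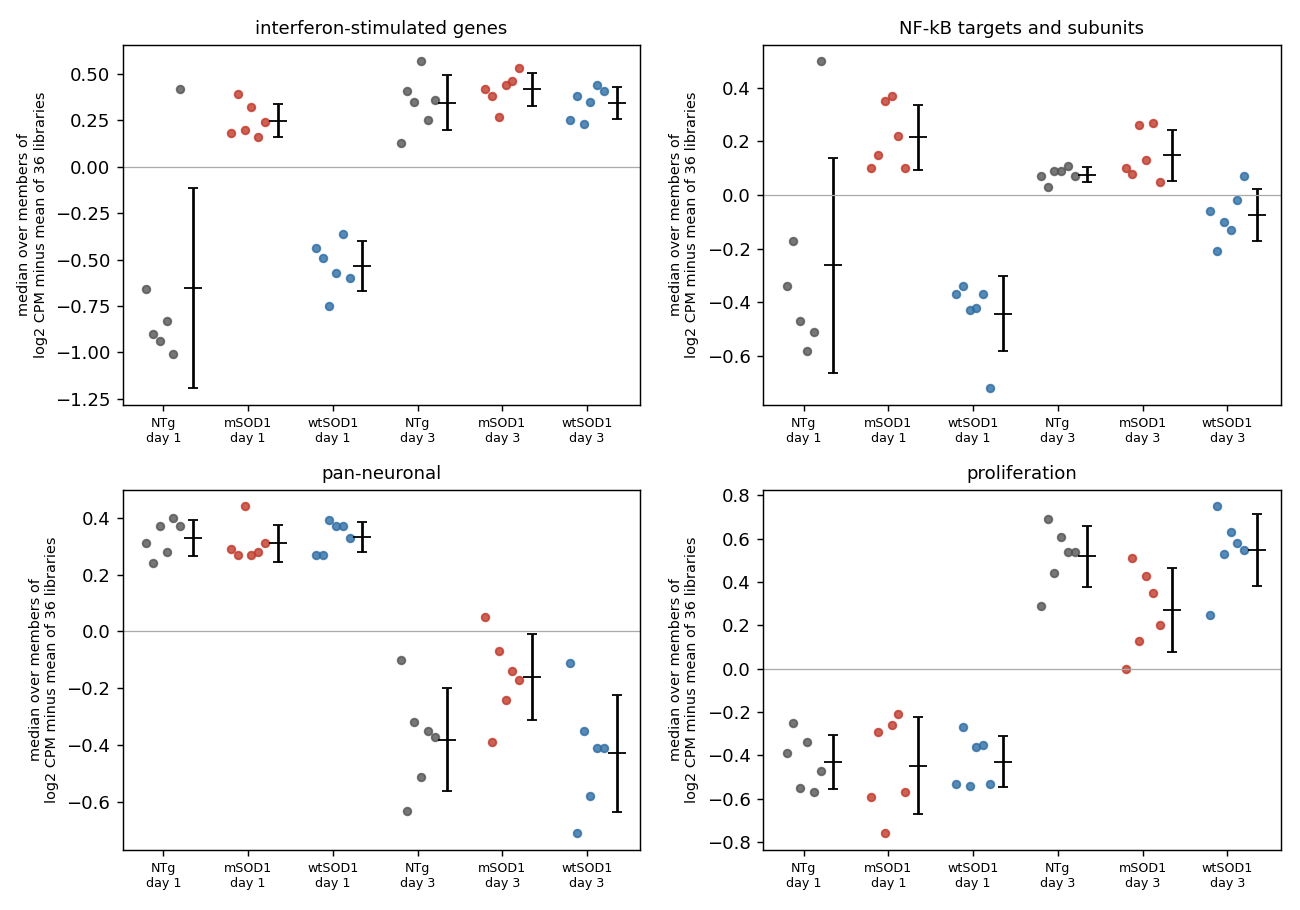
Score of 4 gene lists in each library (y axis, median over members of log2 CPM minus the mean of the 36 libraries) by medium and day (x axis). Dots are libraries in order of experiment 1 to 6 and bars give mean ± SD of 6. The interferon score averaged 0.25 ± 0.09 in mSOD1 and -0.65 ± 0.54 in NTg medium on day 1.

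Did over-expressed wild-type SOD1 in the astrocytes matter on day 1? The cholesterol and fatty acid lists were lower as sets than in NTg medium. Sqle (20775), which oxidises squalene on the way to cholesterol, fell by 0.26 ± 0.04 (adjusted p = 0.00213, 6 of 6 pairs). Scd2 (20250), a fatty acid desaturase, fell by 0.26 ± 0.04 (0.00213, 6 of 6) and Insig1 by 0.23 ± 0.04 (0.0437, 6 of 6). In edgeR without a block, Irf9 alone of the 15207 genes tested rose (0.39 ± 0.07, 0.023, 6 of 6), against 3 genes with the block and 5 with DESeq2. Of 24 cholesterol genes 2 fell and 22 did not pass (20 fell over the list alone, 2.56e-36, adjusted p = 0.00174 with an estimated correlation). Of 13 fatty acid genes 1 fell (6 over the list alone, 4.31e-11, adjusted p = 0.000139 with an estimated correlation). Immediate-early genes, which answer neuronal activity, were higher as a set (3 over the list alone, 5.86e-07, adjusted p = 0.034 with an estimated correlation). Among them Npas4 (225872) stood at 0.68 ± 0.16 (0.178, 0.0201 with the block) and Fos (14281) at 0.45 ± 0.10 (0.0901, 0.0287 with the block). The amino acid response was higher as a set (4 over the list alone, 3.19e-12, adjusted p = 0.0511 with an estimated correlation), with Mthfd2 at 0.26 ± 0.06 (0.178). Of 23 interferon-stimulated genes 1 rose (3 over the list alone, 0.00418, adjusted p = 0.558 with an estimated correlation). Without the pair of libraries that stood apart 1 rose as well, and the list was higher as a set (camera adjusted p = 3.48e-12 at the preset correlation). Its median log2 difference was then 0.29, against 1.04 for mSOD1 medium.

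Some sets of day 1 in wtSOD1 medium held no gene that passed. Hox genes were lower as a set (0.0046, adjusted p = 0.298 with an estimated correlation), with Hoxc4 at -0.26 ± 0.10 (0.642). Oligodendrocyte genes were lower (2.96e-05, adjusted p = 0.278 with an estimated correlation), and potassium channels differed (0.0355, adjusted p = 0.673 with an estimated correlation), with Kcnn2 at 0.21 ± 0.08 (0.732). Without NTg replicate 6 and wtSOD1 replicate 4 these calls of oligodendrocyte genes (0.136) and potassium channels (0.673) were lost.

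Only 4 genes passed for wtSOD1 against NTg on day 1, 9 with replicate as a block, 15 with DESeq2 and 2 without wtSOD1 replicate 4, when the calls of Irf9 (0.36, adjusted p = 0.176) and Insig1 (-0.22, adjusted p = 0.195) were lost and their folds hardly moved. Leaving out whole experiments gave 0 genes (without 3) to 4 (without 1), with 867 genes at unadjusted p below 0.05 in edgeR. Tmem30c (71027), a subunit of lipid flippases, had the largest estimate, 4.78 ± 1.08 (0.156, higher in 4 of 6 pairs), owing to 95.3 CPM in wtSOD1 replicate 4 against 0.304 to 0.922 in the other 5. Mnx1 (-0.09 ± 0.12), Isl1 (-0.06 ± 0.10), Chat (0.01 ± 0.10), Mki67 (-0.02 ± 0.11), Nfkbia (-0.16 ± 0.21) and Sod1 (-0.03 ± 0.08) did not pass.

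Which genes answered wtSOD1 medium on day 3? Cholesterol exporters and enzymes of fatty acid synthesis were among the 15 genes that passed. Abcg1 (11307) and Abca1 (11303), which export cholesterol, fell by 1.15 ± 0.10 (adjusted p = 1.96e-10) and 0.77 ± 0.09 (3.34e-06), the latter from 269 ± 23 to 158 ± 9.1 CPM. Scd1 fell by 0.62 ± 0.07 (9.53e-07), Srebf1, a regulator of fatty acid genes that overlaps Rai1, by 0.57 ± 0.07 (3.34e-06), Scd2 by 0.35 ± 0.04 (1.43e-06) and Rnf145, a sterol-regulated ubiquitin ligase, by 0.27 ± 0.04 (2.24e-05). Fasn, the fatty acid synthase (-0.23 ± 0.05, 0.0241), Acsl3, which activates fatty acids and overlaps Utp14b (-0.19 ± 0.04, 0.0314), and Ddc, which makes dopamine and serotonin (-0.48 ± 0.09, 0.00554), completed the 9 falls, each in 6 of 6 pairs. The 6 rises, also in 6 of 6 pairs, were of the carriers Slc16a9 (0.57 ± 0.11, 0.00554), Slc16a6 (0.42 ± 0.07, 0.000298) and Slc43a2 (0.31 ± 0.07, 0.0365), and of Arsg, a sulfatase gene that overlaps Slc16a6 (0.41 ± 0.09, 0.0301). The others were Arrdc3, which helps internalise receptors (0.44 ± 0.08, 0.00554), and B3gnt5, which builds glycolipids (0.17 ± 0.03, 0.0137). Leaving out experiments 1, 3, 4 or 5 left 8, 8, 9 and 8 genes, of which 2, 1, 2 and 1 rose. Of 13 fatty acid genes 5 fell and 8 did not pass (7 fell over the list alone, 3.61e-34, adjusted p = 5.29e-09 with an estimated correlation).

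Other lists moved as sets in wtSOD1 medium on day 3 without a member that passed, and all lost the call with an estimated correlation. The amino acid response was higher (7.83e-06, adjusted p = 0.29 with an estimated correlation), with Slc7a5 at 0.23 ± 0.06 (0.317, 0.0354 with the block), as were cholesterol genes (0.00376, adjusted p = 0.58 with an estimated correlation), with Idi1 at 0.16 ± 0.05. Mesenchyme was lower (0.000562, adjusted p = 0.466 with an estimated correlation), with Postn at -0.56 ± 0.13 (0.119, 0.0185 with the block). Oligodendrocyte genes were lower (0.00224, adjusted p = 0.424 with an estimated correlation), with Gm98 at -0.50 ± 0.12 (0.127, 0.0481 without the pair of libraries that stood apart). NF-kB genes were lower (0.00226, adjusted p = 0.424 with an estimated correlation), with Vcam1 at -0.39 ± 0.09 (0.127, 0.00785 without NTg replicate 6 of day 1). Also lower were Hox genes (0.00422, adjusted p = 0.29 with an estimated correlation), with Hoxb6 at -0.27 ± 0.13, and muscle genes (0.012, adjusted p = 0.0972 with an estimated correlation), with Actc1 at -0.73 ± 0.25. Ribosomal proteins (0.0192, adjusted p = 0.856 with an estimated correlation), with Rpl22 at -0.07 ± 0.04, and motor neuron identity genes (0.02, adjusted p = 0.454 with an estimated correlation), with Lhx3 at -0.39 ± 0.20, were lower too. Mnx1 (-0.12 ± 0.14), Isl1 (-0.05 ± 0.11), Chat (-0.08 ± 0.11), Mki67 (0.09 ± 0.11), Nfkbia (-0.22 ± 0.20), Col1a1 (-0.30 ± 0.17), Gfap (-0.82 ± 0.57) and Sod1 (-0.10 ± 0.08) did not pass.

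**Figure D3:**
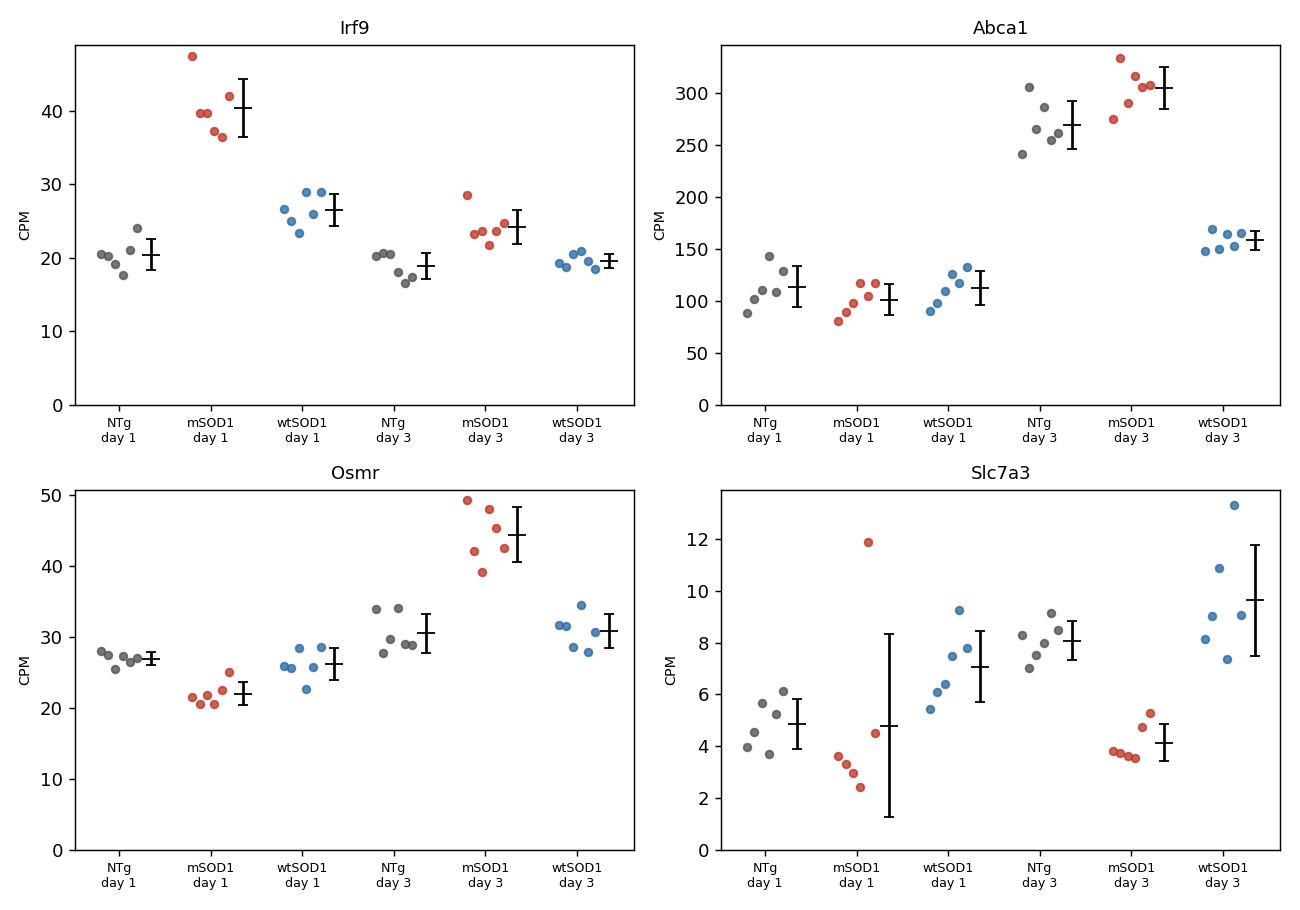
CPM (y axis) of Irf9, Abca1, Osmr and Slc7a3 in each library by medium and day (x axis). Dots are libraries in order of experiment 1 to 6 and bars give mean ± SD of 6. Abca1 averaged 269 ± 23 CPM in NTg and 158 ± 9.1 CPM in wtSOD1 medium on day 3.

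Did mSOD1 and wtSOD1 media move the same genes away from NTg? The comparisons share their NTg libraries, so the answer was set beside simulated data without any effect, and beside others in which each medium had effects but none were shared. In fits of the 18 libraries of day 1, 50 genes passed for mSOD1 and 3 for wtSOD1, and 0 passed for both in edgeR (expected 0.0034 from the sizes, 0 in simulations). With replicate as a block, 1 gene passed for both in the same direction and 1 in opposite directions. In the fit of all libraries 64 and 4 genes passed on day 1, and there Irf9 rose and Insig1 fell in both media. The overlap on day 1 thus depended on the fit, and the wtSOD1 calls of both genes were lost without wtSOD1 replicate 4. In that fit 1058 and 867 genes had an unadjusted p below 0.05. On day 3, 553 and 23 passed, 4 for both in the same direction and 1 in opposite directions (expected 0.398, 0 in simulations without effects, at most 1 and 1 in those with effects not shared). Simulations without effects called means of 0.2 and 0.2 genes on day 1 and 0 and 0.1 on day 3. Their overlap of 0 is thus no yardstick for the overlap seen. Those with effects not shared called means of 318 and 14.9 genes on day 3. With replicate as a block it was 145 in the same and 41 in opposite directions. Simulations of that fit with effects not shared gave means of 29 and 19.4 (at most 37 and 27), with 3290 and 185 genes called where the data gave 4273 and 313. With 3 NTg libraries for each comparison the overlap of day 3 was 0 and 2 in the same direction. The fit with 0 called 12 genes for mSOD1 and 13 for wtSOD1, and the fit with 2 called 1298 and 10. Covariance of the log2 differences was 0.0113 on day 1 (simulated 0.013) and 0.00662 on day 3 (simulated 0.00776). When mSOD1 was set against NTg replicates 1, 3 and 5 and wtSOD1 against 2, 4 and 6, the covariance was -0.00444 on day 1 and 0.00543 on day 3, and with the NTg libraries exchanged -0.00209 and -0.0104.

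How did mutant and wild-type SOD1 astrocyte media differ on day 1? The interferon and NF-kB lists were again higher as sets in mSOD1 medium. Ccl2 was higher by 3.58 ± 0.34 (adjusted p = 4.14e-08), Cxcl10 by 3.17 ± 0.39 (2.96e-06), Usp18 by 2.14 ± 0.20 (6.48e-09), Nfkbia by 1.76 ± 0.20 (3.74e-07) and Irf9 by 0.61 ± 0.07 (3.73e-07), each in 6 of 6 pairs. Birc3, an inhibitor of apoptosis that NF-kB induces, rose by 1.36 ± 0.24 (0.000607), Icam1, an adhesion molecule, by 1.22 ± 0.26 (0.00647) and Irf1, a transcription factor of the interferon response, by 0.87 ± 0.12 (2.78e-05). The immediate-early genes Npas4 and Fos were lower by 1.18 ± 0.17 (2.78e-05) and 0.73 ± 0.10 (1.24e-05). Rem2, a channel-binding GTPase, fell by 0.66 ± 0.13 (0.00507) and Nr4a1 by 0.56 ± 0.12 (0.0123, 0.0703 without wtSOD1 replicate 4), each in 6 of 6 pairs. Fgf3, a growth factor, fell by 0.97 ± 0.20 (0.00673). Without wtSOD1 replicate 4 the calls of Gem (-0.79, 0.118), Ano1 (-0.71, 0.17), Kcnq3 (-0.60, 0.116), Nptx1 (-0.56, 0.204), Gpr3 (-0.62, 0.134), Arhgef6 (-0.48, 0.313) and Ifi202b (1.23, 0.142) were lost, with the directions kept.

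Of 23 interferon-stimulated genes, 14 were higher in mSOD1 than in wtSOD1 medium on day 1 and 9 did not pass (19 over the list alone, 2.53e-53, adjusted p = 3.11e-05 with an estimated correlation). Of 23 NF-kB genes 11 were higher (14 higher and 1 lower over the list alone, 3.61e-34, adjusted p = 6.95e-05 with an estimated correlation). Of 24 p53 targets 1 was higher, Cdkn1a (0.27 ± 0.07, 0.0304, 0.161 without wtSOD1 replicate 4), and the list as a set (0.00177, adjusted p = 0.353 with an estimated correlation). Of 24 cholesterol genes 5 were higher, and 2 without the pair of libraries that stood apart (11 over the list alone, 1.52e-10, adjusted p = 0.158 with an estimated correlation), led by Nsdhl of sterol synthesis (0.28 ± 0.06, 0.00524). Of 13 fatty acid genes 1 was higher, Scd2, by 0.19 ± 0.04 (0.0128, 6 over the list alone, 0.00211, adjusted p = 0.0972 with an estimated correlation). Of 25 amino acid response genes 4 were lower (10 over the list alone, 3.9e-12, adjusted p = 0.0511 with an estimated correlation), led by Mthfd2 (-0.43 ± 0.06, 3.27e-05), and without wtSOD1 replicate 4 the calls of Slc7a1 (0.0609) and Aars (0.0653) were lost. Of 22 immediate-early genes 3 were lower (4 over the list alone, 4.96e-06, adjusted p = 0.05 with an estimated correlation). Of 20 potassium channels 1 was lower (0.00227, adjusted p = 0.545 with an estimated correlation). Glutamate receptors were lower as a set (0.0109, adjusted p = 0.631 with an estimated correlation), with Gria3 at -0.13 ± 0.06 (0.382), and ribosomal proteins higher (0.00746, adjusted p = 0.82 with an estimated correlation), with Rps16 at 0.15 ± 0.07 (0.437). These 3 calls were lost without the pair of libraries that stood apart (0.0921, 0.103 and 0.437). In all, 82 genes were higher and 71 lower, and the 153 became 84 without wtSOD1 replicate 4 (57 higher, 27 lower), 48 without experiment 4 (39 higher, 9 lower) and 234 with the block.

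How did mutant and wild-type SOD1 astrocyte media differ on day 3? The cholesterol exporters Abcg1 and Abca1 were among the genes higher in mSOD1 medium. Both were lower in wtSOD1 than in NTg medium that day, as given above, so this difference need not be a rise in mSOD1 medium. Abcg1 was higher by 1.19 ± 0.10 (adjusted p = 1.02e-10), Abca1 by 0.95 ± 0.09 (4.62e-08), and Reg3b by 1.31 ± 0.14 (2.35e-07). Csf2rb2 was higher by 1.42 ± 0.20 (2.16e-05), Ifi202b by 1.68 ± 0.29 (0.000379) and Prdm1, a transcriptional repressor, by 0.95 ± 0.13 (1.56e-05), each in 6 of 6 pairs. Osmr (0.53 ± 0.07, 1.99e-06), Lifr (0.48 ± 0.07, 9.03e-05) and Socs2 (0.49 ± 0.07, 2.16e-05) were higher too, as 6 of 17 STAT3 response genes (10 higher and 1 lower over the list alone, 5.68e-10, adjusted p = 0.0106 with an estimated correlation). Slc7a3 was lower by 1.21 ± 0.23 (0.00127), Tcfap2b by 1.20 ± 0.25 (0.00337), Chac1 by 0.98 ± 0.18 (0.001) and Mt2, a metallothionein, by 0.67 ± 0.15 (0.00883). Of 25 amino acid response genes 13 were lower and 12 did not pass (17 over the list alone, 3.13e-19, adjusted p = 0.0105 with an estimated correlation), among them Slc7a5 (-0.54 ± 0.06, 8.12e-07) and Asns, asparagine synthetase (-0.33 ± 0.06, 0.000672). Of 24 unfolded protein response genes 3 were lower (9 over the list alone, 0.000245, adjusted p = 0.244 with an estimated correlation). Moxd1 was at the threshold (-0.68 ± 0.20, 0.0498), and lost its call without NTg replicate 6 (0.0511) or wtSOD1 replicate 4 (0.0527) of day 1.

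The pan-neuronal and motor neuron lists were higher and the proliferation list lower as sets in mSOD1 than in wtSOD1 medium on day 3, and all lost the call with an estimated correlation. Of 22 pan-neuronal genes 6 were higher and 16 did not pass (16 over the list alone, 1.59e-13, adjusted p = 0.263 with an estimated correlation), including Stmn2 (0.40 ± 0.08, 0.00197) and the neurofilament Nefh, which overlaps Ap1b1 (0.51 ± 0.12, 0.0125). Of 24 motor neuron identity genes 4 were higher, Gfra1 by 0.55 ± 0.09 (0.00048), Nrg1 by 0.35 ± 0.08 (0.00494), the GDNF receptor Ret by 0.28 ± 0.08 (0.032) and peripherin, Prph, by 0.41 ± 0.11 (0.0343). Over that list alone 7 were higher (0.000976, adjusted p = 0.28 with an estimated correlation). Chat stood at 0.36 ± 0.11 (0.051, 0.00315 with the block) and Mki67 at -0.31 ± 0.11 (0.107, 0.000616 with the block). Chat also passed without NTg replicate 6 of day 1 (0.0425) and without the pair of libraries that stood apart (0.0441). Of 31 proliferation genes 8 were lower (28 over the list alone, 4.12e-20, adjusted p = 0.263 with an estimated correlation). Of 24 axon injury genes 4 were higher (10 over the list alone, 1.72e-05, adjusted p = 0.166 with an estimated correlation). Of 31 axon guidance genes 5 were higher and 1 lower (13 and 2 over the list alone, 0.000151, adjusted p = 0.35 with an estimated correlation).

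Channel and synapse genes were higher as sets with few members past the threshold. These were sodium and calcium channels (1 of 20 higher, 1.75e-06, adjusted p = 0.376 with an estimated correlation) and synaptic vesicle genes (2 of 22, 4.56e-05, adjusted p = 0.458 with an estimated correlation). Potassium channels (1 of 20, 0.00252, adjusted p = 0.545 with an estimated correlation) and glutamate receptors (1 of 16, 0.00359, adjusted p = 0.58 with an estimated correlation) followed. Of 13 fatty acid genes 3 were higher (0.00313, adjusted p = 0.118 with an estimated correlation). Of 23 NF-kB genes 2 were higher, Vcam1 by 0.63 ± 0.09 and Bcl3 by 0.74 ± 0.13 (0.00451, adjusted p = 0.458 with an estimated correlation). Cholesterol genes were mixed, 1 higher and 2 lower of 24 (0.0047, adjusted p = 0.593 with an estimated correlation). Ribosomal proteins (0.000757, adjusted p = 0.721 with an estimated correlation), progenitor genes (0.00265, adjusted p = 0.58 with an estimated correlation) and NRF2 targets (0.0307, adjusted p = 0.58 with an estimated correlation) were lower as sets. Of 18 mesenchyme genes 2 were lower (0.0457, adjusted p = 0.711 with an estimated correlation, 0.0627 without the pair of libraries that stood apart). In all, 379 genes were higher and 137 lower, and the 516 became 166 without replicate 6 and 657 without replicate 1, and 1418 with the block.

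What changed between days 1 and 3 in every medium? Most genes of the motor neuron list fell, and most of the proliferation, astrocyte and mesenchyme lists rose. Whether the share of cells or the expression within cells changed over time was not tested. Mnx1 fell by 1.69 ± 0.13, 1.55 and 1.73 in NTg, mSOD1 and wtSOD1 medium, Isl1 by 1.48, 1.39 and 1.47, and Chat by 1.45, 1.13 and 1.54, each in 6 of 6 pairs. Mki67 rose by 1.11, 1.02 and 1.23, the astrocyte filament Gfap (14580) by 3.71 (in 5 of 6 pairs), 3.49 and 2.91, and the collagen Col1a1 by 0.97, 0.79 and 0.64 (in 5 of 6 pairs). The rises of Gfap start near the floor, with 1.18 CPM in NTg replicate 6 and 0.244 CPM in mSOD1 replicate 2 of day 1. On day 3 NTg replicate 2 held 3.47 CPM. Among the largest rises were Lbp, a lipopolysaccharide-binding protein (4.62, 4.58 and 4.05), Osr1, a transcription factor of mesoderm (4.42, 4.46 and 4.06), and Aldh1a2, a motor neuron list member that makes retinoic acid (4.06, 3.94 and 4.22). Isl2, a motor neuron factor (-2.53, -2.22 and -2.42), and Rem2 (-2.74, -2.37 and -3.08) were among the largest falls. In edgeR 9360, 8587 and 9396 genes passed in NTg, mSOD1 and wtSOD1 medium, and 3525 rose and 3358 fell in all 3 media, where 413 and 403 were expected from independent lists. Nfkbia fell in mSOD1 medium (-1.30) and did not pass in NTg (0.23) and wtSOD1 medium (0.17), and Cxcl10 (-2.81), Usp18 (-2.35) and Ccl2 (-2.09) fell in mSOD1 medium. Without NTg replicate 6 of day 1 Gfap rose by 5.76 in NTg medium, and without wtSOD1 replicate 4 Gfap and Lbp rose by 4.78 and 5.05 in wtSOD1 medium. Sod1 did not pass in any of the 3 media (0.03, -0.10 and -0.04).

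Lists over time went the same way in the 3 media, given in the order NTg, mSOD1 and wtSOD1. Those named here passed with camera at the preset correlation. Of 31 proliferation genes 31, 29 and 31 rose (adjusted p = 0.353, 0.458 and 0.348 with an estimated correlation). Of 18 mesenchyme genes 16, 15 and 15 rose (adjusted p = 0.0972, 0.135 and 0.164 with an estimated correlation). Of 17 astrocyte genes 13, 14 and 14 rose and 2 fell in each, including Aldh1l1 by 3.24, 2.92 and 3.24 (adjusted p = 0.263, 0.135 and 0.166 with an estimated correlation). Of 24 p53 targets 19, 18 and 19 rose and 3 fell in each, such as Ccng1, a cyclin of the damage response (1.41, 1.20 and 1.45), with adjusted p = 0.0439 in NTg medium and 0.0587 and 0.0529 in the others with an estimated correlation. Of 22 pan-neuronal genes 19, 18 and 19 fell and 2, 2 and 1 rose (adjusted p = 0.407, 0.58 and 0.376 with an estimated correlation). Of 24 motor neuron identity genes 16, 15 and 15 fell and 3, 3 and 2 rose (adjusted p = 0.0972, 0.135 and 0.1 with an estimated correlation). Of 21 spinal interneuron genes 19, 17 and 18 fell and 0, 1 and 0 rose (adjusted p = 0.263, 0.345 and 0.333 with an estimated correlation).

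Lipid, stress and activity lists changed over time in some or all media. Cholesterol genes fell in NTg and mSOD1 medium (19 and 18 of 24, adjusted p = 0.376 and 0.353 with an estimated correlation). Fatty acid genes were higher as a set in each medium (7, 7 and 8 of 13 rose and 3, 2 and 2 fell, adjusted p = 0.135, 0.197 and 0.326 with an estimated correlation), though not in wtSOD1 medium with the block (0.0726). Heat shock genes were higher too (10 of 18 rose in each and 1, 2 and 1 fell, adjusted p = 0.454, 0.454 and 0.494 with an estimated correlation). The following sets passed in NTg and wtSOD1 medium. Interferon genes were higher (14 of 23 rose in both, 0 and 3 fell, adjusted p = 0.482 and 0.532 with an estimated correlation), as were NRF2 targets (13 of 23 rose and 4 fell in both, adjusted p = 0.528 and 0.58 with an estimated correlation, 0.0608 in wtSOD1 medium without the pair of libraries that stood apart). Immediate-early genes (15 of 22 fell in both, 5 and 3 rose, adjusted p = 0.399 and 0.175 with an estimated correlation) and sodium and calcium channels (14 and 15 of 20 fell, 1 and 2 rose, adjusted p = 0.604 and 0.638 with an estimated correlation) were lower. Synaptic vesicle (16 of 22 fell in both, 3 and 4 rose, adjusted p = 0.631 and 0.621 with an estimated correlation) and axon guidance genes (17 of 31 fell in both, 10 and 9 rose, adjusted p = 0.558 and 0.58 with an estimated correlation) were mixed but lower as sets. The fall of Tmem30c in wtSOD1 medium (-4.82) turned to 0.03 without wtSOD1 replicate 4.

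Which media differences changed between day 1 and day 3? Against NTg, the mSOD1 difference moved down for 7 interferon genes and up for Osmr and Rdh10. Usp18 moved by -2.46 (adjusted p = 1.09e-05), Ifih1 by -1.49, Bst2, which tethers viruses, by -1.28, Ddx58 by -1.03, Irf1 by -0.96, Irf9 by -0.65 (0.000628) and Nfkbia by -1.53 ± 0.28 (0.00636, in 5 of 6 pairs). Rnd1, a regulator of cell shape, and Crhbp, which binds corticotropin-releasing hormone, moved by -1.15 and -0.96. Osmr moved by 0.82 (2.72e-06), from -0.28 on day 1 (0.0528, 0.0402 with the block) to 0.53 on day 3, and Rdh10 (98711), which oxidises retinol, by 0.69 (0.000628). Of 23 interferon-stimulated genes 7 moved down and 16 did not pass, and 12 moved down without the pair of libraries that stood apart (14 over the list alone, 7.23e-22, adjusted p = 0.0105 with an estimated correlation). The score of this list did not fall in mSOD1 medium (0.16 to 0.39 on day 1, 0.27 to 0.53 on day 3), although Cxcl10, Usp18 and Ccl2 fell there. In NTg medium it rose, from -1.01 to -0.66 on day 1 (0.42 in replicate 6) to 0.13 to 0.57 on day 3. For the list, the scores thus drew together with a rise in NTg medium. The score rose in wtSOD1 medium as well. Whether the effect of mSOD1 medium faded against a rise over time common to all media was not tested. Of 23 NF-kB genes 4 moved down, and 8 without that pair (13 over the list alone, 8.52e-11, adjusted p = 0.05 with an estimated correlation). The 35 genes (13 up, 22 down) became 8 without experiment 4, 38 without experiment 1, 56 without NTg replicate 6 of day 1 and 406 with the block, where 277 were up and 129 down. Of 19 lists called, 1 kept its call with an estimated correlation.

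Against wtSOD1, the mSOD1 difference moved up for Abca1 and Abcg1 and down for Ccl2 and Usp18. Since both exporters were lower in wtSOD1 than in NTg medium on day 3, their move need not be a rise in mSOD1 medium. Abca1 moved by 1.09 (adjusted p = 5.97e-06), Abcg1 by 1.02, Rdh10 by 0.88 (5.97e-06), Osmr by 0.76 (5.97e-06), Prdm1 by 1.20, Csf2rb2 by 1.88, Nek7, a kinase of mitosis, by 0.60 and Pcsk2, which processes neuropeptides, by 0.65. Ccl2 moved by -3.15, Usp18 by -2.17 (3.76e-05) and Nfkbia by -1.47 ± 0.28 (0.0084). Of 23 interferon-stimulated genes 4 moved down (13 over the list alone, 2.12e-16, adjusted p = 0.034 with an estimated correlation), and of 24 cholesterol genes 3 (14 over the list alone, 5e-11, adjusted p = 0.135 with an estimated correlation). The interferon score rose in wtSOD1 medium, from -0.75 to -0.36 on day 1 to 0.23 to 0.44 on day 3. Of 22 immediate-early genes 2 moved up (9 over the list alone, 5.52e-06, adjusted p = 0.05 with an estimated correlation), and of 17 STAT3 response genes 3, or 1 without the pair of libraries that stood apart (8 over the list alone, 1.7e-05, adjusted p = 0.0972 with an estimated correlation). Without wtSOD1 replicate 4 the calls of Irf7 (-1.84, 0.0735), Nfkb2 (-0.50, 0.0524), Insig1 (-0.28, 0.0536), Nsdhl (-0.35, 0.0559) and Sqle (-0.23, 0.096) were lost, with the directions kept. So were those of Fosl2 (0.39, 0.0666), Bcl3 (0.71, 0.07), Socs2 (0.39, 0.0735) and Ephb1 (0.50, 0.078). The 90 genes (69 up, 21 down) became 31 without that library, 17 without experiment 4, 206 without experiment 1 and 599 with the block, and of 19 lists called, 1 kept its call with an estimated correlation.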

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

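The tests of glial RNA, of a wrong label, of exchanged labels, of ribosomal RNA-like reads, of fewer non-neuronal cells and of a slower change were chosen after the results were seen. The tests of low depth, few molecules, gene length and of other splits of the libraries were set before theirs. Within groups of 6, single libraries lay far from the others in 9 of 66 groups of values, where chance flags about 1 in 20 groups. These were the read totals of wtSOD1 replicate 4 of day 1 (88.9 M), NTg replicate 1 of day 3 (42.2 M) and wtSOD1 replicate 2 of day 3 (23.1 M), and the genes detected in NTg replicate 1 (18506) and mSOD1 replicate 3 (17839) of day 3. Gfap stood apart in NTg replicate 6 (1.18 CPM) and mSOD1 replicate 2 (0.244 CPM) of day 1 and NTg replicate 2 of day 3 (3.47 CPM), and Nfkbia in NTg replicate 6 of day 1 (19.3 CPM). The interaction tests found media differences that changed between days for 35 genes against NTg and 90 against wtSOD1. Against NTg they were led by Osmr (0.82), Usp18 (-2.46), Ddx58 (-1.03), Irf9 (-0.65), Rdh10 (0.69), Rnd1 (-1.15), Ifih1 (-1.49), Irf1 (-0.96), Crhbp (-0.96) and Bst2 (-1.28). Against wtSOD1 they were led by Rdh10 (0.88), Osmr (0.76), Abca1 (1.09), Nek7 (0.60), Usp18 (-2.17), Abcg1 (1.02), Prdm1 (1.20), Ccl2 (-3.15), Csf2rb2 (1.88) and Pcsk2 (0.65).

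NTg replicate 6 of day 1 stood apart on a principal component and had the fewest reads, and low depth is argued against: the other 5 libraries, thinned to its 4.39 M reads, lay at most 0.384 from the mean of the rest, and the library itself 0.496. RNA of glial cells may have entered it, as 28 of 36 glial genes were higher there than in each of the other 5 (10 of 12 oligodendrocyte, 6 of 7 microglial, 12 of 17 astrocyte genes), with Mbp at 55.9, Ctss at 29, Apoe at 22.2, C1qb at 8.96 and Gfap at 1.18. A first form of this test asked for a median log2 difference above 1 and gave 0.70, which decided nothing, and 27 of the 36 genes exceed 1 CPM in the other 5 libraries as well. Cells were sorted for CD2, but how completely this removed glial cells is not given in the sources used here. The microglial list score was 2.42 there, against 0.47 in the next highest library, wtSOD1 replicate 4 of day 1. The oligodendrocyte score was 1.14, against 0.24 in NTg replicate 1 of day 3, the next highest. An exchange of labels with an mSOD1 library is argued against: each of the 6, mSOD1 replicate 6 included (median 0.2), lay at least 0.65 above the highest of the other NTg libraries (SD 0.11) over genes called higher in mSOD1 medium without it. A single mSOD1 library under the wrong label stays open: over the 78 genes called higher in mSOD1 medium without NTg replicate 6, that library had a median of 0.17, against 0.01 to 0.35 in mSOD1 and -0.86 to -0.61 in the other NTg libraries. Glial RNA and a wrong label could not be told apart for those 78 genes. Its glial genes, 0.83 above the highest mSOD1 library, decide nothing on the label, as their scores overlap between mSOD1 (-0.46 to -0.2) and the other NTg libraries (-0.44 to -0.15).

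wtSOD1 replicate 4 of day 1 had the most reads and stood apart on another component. Few starting molecules stay open: of 873 genes at 1 to 2 CPM in the other 5 libraries, 0.916% had no read there, which lay between the bounds set for and against (1% and 0.1%) and decided nothing. In the other 5, with 10.5 to 20.7 M reads each, the share was 0 to 0.349%. This library also had the fewest genes detected of its group (16829) despite 88.9 M reads. Both values go with few molecules, but no bound had been set for them. A further test, added after the value of 0.916%, found that genes at 1 to 2 CPM scattered by 0.871 around the mean of the other libraries, against 0.503 to 0.631 in the other 5. Genes over 100 CPM scattered more there as well (0.195 against 0.0753 to 0.151), which does not tell few molecules from a general departure of this library. Reads at ribosomal RNA-like stretches are argued against as the cause, since 2610528E23Rik was 1.03 times the highest of the other 35 libraries. No biological explanation was tested.

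Neuronal lists were higher and proliferation and mesenchyme lists lower as sets in mSOD1 medium after 3 days, at the preset correlation. A lower share of non-neuronal cells stays open: by means over members the pan-neuronal list rose more than the motor neuron list in 6 of 6 pairs (difference 0.19, SD 0.09, exact p = 0.0312), and by medians of member differences in 6 of 6 as well (0.14, SD 0.09, exact p = 0.0312), but by library medians in 5 of 6 (0.14, SD 0.13, exact p = 0.0938), both added later, and astrocyte and mesenchyme lists differed by 0.18 (SD 0.21, exact p = 0.125). A slower change over time by the same part in every list is argued against as the whole cause. The part was that of the pan-neuronal list, and changes over time were taken from wtSOD1 medium. The astrocyte list lay 0.48 (SD 0.1) above the level this gave in 6 of 6 pairs (exact p = 0.0312, the smallest that 6 pairs can give). It lay 0.32 (SD 0.15) above by library medians and 0.39 (SD 0.04) by medians of member differences, each in 6 of 6 as well. A delay that differs between lists or cell types was not tested. Gene length is argued against, since the pan-neuronal list kept a camera p of 1.57e-15 (9.12e-16 before) after a fit on length, both at the preset correlation, though the list had adjusted p = 0.344 with an estimated correlation. A direct effect of mSOD1 medium on neuronal genes and on dividing cells stays open beside a change in the share of cells or in a single cell type.

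Other splits of the same libraries were set beside the real one to ask how often chance gives as many genes. Among 100 splits including the real one, as many genes as the real split came from 2 for mSOD1 against NTg on day 1 (real 64, highest other 65), 3 on day 3 (443, 1760), 2 for wtSOD1 against NTg on day 3 (15, 414), 2 for mSOD1 against wtSOD1 on day 1 (153, 224) and 1 on day 3 (516, 245). For mSOD1 against wtSOD1 on day 3 only the real split reached its count, which argues against chance. In the rest of these comparisons 2 or 3 splits did, so such counts were rare by chance, but chance is not excluded. For wtSOD1 against NTg on day 1 chance stays open, as 13 splits gave 4 genes or more (highest other 310). The splits with 1760, 414 and 310 genes, several times the real counts, point to a structure of the samples: they parted 4, 2 and 0 of the 6 same-numbered pairs, the last of them thus setting whole experiments against each other, and the cause was not tested. Changes over time (9360, 8587 and 9396, highest others 7290, 6554 and 6462) and the interactions (35 and 90, highest others 6 and 2) were reached by 1 split, the real one, which argues against chance. Among the 32 splits that part every pair, only the real one reached its count in 10 comparisons, the highest others being 47, 0, 1, 17, 0, 7018, 6452, 7202, 18 and 23 in the order used above. For wtSOD1 against NTg on day 1, 3 of the 32 did (highest other 5).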

How the results depend on the processing

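Directions of results that passed were mostly stable, and counts of genes were not. The alternatives that leave out NTg replicate 6 or wtSOD1 replicate 4 of day 1, the block within each day and the authors' log2-like values were chosen after the data were seen. Of 737 named results, 461 passed the threshold and 321 of these did so under every alternative that was run for them. Of 12250 values, 11236 (91.7%) stayed the same: they kept call and direction or, without a call in either fit, moved by at most their standard error. A further 657 lost the call, 274 gained it, 81 without a call moved by more, and 2 with a call turned. A turn without a call was not counted as such: Tmem30c for wtSOD1 against NTg on day 1 went from a positive estimate to -0.08 without wtSOD1 replicate 4. Changes over time passed for 8547 to 9051 genes in NTg, 7764 to 8320 in mSOD1 and 8646 to 9201 in wtSOD1 medium when each replicate was left out. Experiment as a block (paired libraries) gave 1511 genes instead of 443 for mSOD1 against NTg on day 3, 9 instead of 4 for wtSOD1 against NTg on day 1, 234 instead of 153 and 1418 instead of 516 for mSOD1 against wtSOD1 on days 1 and 3, and 406 instead of 35 and 599 instead of 90 for the interactions against NTg and wtSOD1. In fits of the libraries of each day it changed the overlap with shared controls from 0 to 1 on day 1 and from 4 to 145 on day 3. It added calls of 69 named results and 13 lists, ended 2 list calls and changed no other call among these results and lists. Of all genes it kept 63 of 64, 152 of 153 and 9329 of 9360 calls for mSOD1 against NTg and wtSOD1 on day 1 and over time in NTg medium. The cause of each change was not tested. A block within each day gave 189, 2758, 56, 56, 577 and 2366 genes for mSOD1 against NTg, wtSOD1 against NTg and mSOD1 against wtSOD1 (day 1 then day 3 each), and 1680 and 1649 for the interactions.

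Leaving out each replicate in turn gave 32 to 388 genes for mSOD1 against NTg on day 3, 0 to 4 and 8 to 12 for wtSOD1 against NTg on days 1 and 3, 48 to 123 and 166 to 657 for mSOD1 against wtSOD1, and 8 to 38 and 17 to 206 for the interactions against NTg and wtSOD1. Fits of fewer libraries have less power by construction, yet the gain without replicate 1 was not explained, and the cause was not tested. For mSOD1 against NTg on day 1 the range was 49 to 70. With 1 of the libraries below left out, the highest counts were 554 for mSOD1 against NTg on day 3, 19 for wtSOD1 against NTg on day 3 and 174 for mSOD1 against wtSOD1 on day 1. With both left out they were higher still on day 3, 618 for mSOD1 against NTg, 20 for wtSOD1 against NTg and 664 for mSOD1 against wtSOD1, and 88 for mSOD1 against NTg on day 1. Without NTg replicate 6 of day 1 the counts were 7 for wtSOD1 against NTg on day 1 and 56 for the interaction against NTg. Without wtSOD1 replicate 4 of day 1 they were 2 for wtSOD1 against NTg, 84 for mSOD1 against wtSOD1 on day 1 and 31 for the interaction against wtSOD1. Without both libraries they were 95 for mSOD1 against wtSOD1 on day 1 and 70 for the interaction against NTg. The fall over time (Tmem30c, 3 days vs 1 day, wtSOD1) of -4.82, and of -5.06 without replicate 5, turned to 0.032 without wtSOD1 replicate 4 and to 0.03 without both libraries, because that library carried nearly all of its reads.

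DESeq2 gave 703 genes for mSOD1 against NTg on day 3, 15 for wtSOD1 against NTg on day 1, and 89 and 223 for the interactions. Limma-voom with weights gave 1428 for mSOD1 against NTg on day 3, 28 for wtSOD1 against NTg on day 3, 97 and 1582 for mSOD1 against wtSOD1, and 60 for the interaction against NTg. Fits of only the groups compared gave 35 for mSOD1 against NTg and 1 for wtSOD1 against NTg on day 1, and 65 and 320 for mSOD1 against wtSOD1, with fewer degrees of freedom by construction. Without a filter 288 genes passed for mSOD1 against NTg on day 3, and the authors' log2-like values gave 2 for wtSOD1 against NTg on day 1; for these and the tools above the cause was not tested. DESeq2 size factors kept every count within 1.5 times, moved the share of higher genes by at most 8.3 points and turned 0 calls. With 3 NTg libraries for each comparison the overlap on day 3 was 0 and 2. Of 151 calls among 429 list tests, 14 held with an estimated correlation, 149 with the block and 93 with fry; a high correlation among the members of a list widens its error by construction.

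Lists called only with the block were spinal interneuron (0.0417) and glutamate receptors (0.0492) for mSOD1 against NTg on day 1, motor neuron identity (0.0389) and Hox genes (0.0482) on day 3, motor neuron identity (0.0271) and proliferation (0.0205) for wtSOD1 against NTg on days 1 and 3, and motor neuron identity (0.0251) and progenitor genes (0.0278) for the interaction against NTg. Over time they were progenitor (0.0124, 0.0211) and axon injury genes (0.0467, 0.0211) in NTg and wtSOD1 medium and NRF2 targets in mSOD1 medium (0.0165). The block ended the calls of heat shock genes for mSOD1 against NTg on day 3 (0.0695) and of fatty acid genes over time in wtSOD1 medium (0.0726). Depth limits the smallest library most: NTg replicate 6 of day 1 held 4.39 M reads, and genes below about 1 CPM rest there on few reads. Tests with 6 libraries per group missed some simulated small changes, so a gene that did not pass is not shown to be unchanged.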

Other observations

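Genes mutated in familial ALS gave no call between media, in lists and tests planned before the data were seen; only the level of the pair of genes in the last paragraph, and the values without NTg replicate 6 and wtSOD1 replicate 4 of day 1, were looked up after the results were seen. Of 29 such genes, 0 passed in edgeR in the 6 comparisons between media (174 gene tests, 17 at unadjusted p below 0.05, 0 with DESeq2), and the lowest adjusted p of the list was 0.124. Without the pair of libraries named above 1 fell for mSOD1 against wtSOD1 on day 3, so an effect is not shown to be absent. Over time 10, 9 and 11 of them rose and 10, 8 and 8 fell in NTg, mSOD1 and wtSOD1 medium. Regulators of apoptosis and necroptosis gave 0 in edgeR between media (174 gene tests of 29 genes, 16 at unadjusted p below 0.05, 1 with DESeq2), and 1 fell for mSOD1 against NTg on day 3 without the pair of libraries. Their lowest adjusted p as a list was 0.0538, for wtSOD1 against NTg on day 3 (0.0386 without the pair of libraries). Over time 16, 15 and 16 of them rose and 8, 6 and 8 fell. Enzymes that remove superoxide and peroxide gave 0 of 78 gene tests in edgeR (7 at unadjusted p below 0.05, 1 with DESeq2; 1 rose for mSOD1 against NTg on day 3 without the pair of libraries), with a lowest list value of 0.464, and astrocyte genes gave 0 of 102 between media (10 at unadjusted p below 0.05, 1 with DESeq2).

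Lists of other cells and states passed as sets in 0 of 11 comparisons with camera. Their lowest adjusted p-values were 0.102 for hypoxia and glycolysis (2 of 168 gene tests between media passed), 0.126 for lysosome and autophagy (2 of 174), 0.0656 for microglia and macrophages, 0.244 for neural crest and sensory neurons (2 of 84), 0.368 for pluripotency, 0.405 for endoderm (1 of 66) and 0.703 for endothelium. Oxidative phosphorylation passed in the interaction of time with mSOD1 against NTg (0.0296, adjusted p = 0.817 with an estimated correlation). The erythroid list had 1 tested member and was not tested as a set. Without NTg replicate 6 and wtSOD1 replicate 4 of day 1, further lists passed: fatty acid genes for mSOD1 against NTg on day 1 (0.0204), oxidative phosphorylation (0.0436) and lysosome genes (0.0248) for wtSOD1 against NTg on day 1, interferon genes for mSOD1 against wtSOD1 on day 3 (0.0286), NF-kB genes over time in NTg medium (0.0205) and progenitor genes in the interaction against wtSOD1 (0.0376). In that interaction the calls of p53 targets (0.0208 to 0.0504), the unfolded protein response (0.0332 to 0.0684), the amino acid response (0.0273 to 0.0827) and NRF2 targets (0.0392 to 0.122) were lost.

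The transcript 2610528E23Rik took a large and variable share of the reads, from 436 CPM in wtSOD1 replicate 6 of day 3 to 13900 CPM in wtSOD1 replicate 4 of day 1. Lars2, a mitochondrial leucine tRNA synthetase, ran from 330 CPM in the same library of day 3 to 9480 CPM in wtSOD1 replicate 6 of day 1, where 2610528E23Rik stood at 13500 CPM.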
